A study of Rattus norvegicus with 6 samples.

How the data were processed

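Total RNA of 6 libraries of the rat breast cancer line RMT1 was sequenced after depletion of ribosomal RNA, with a strand-specific library kit. There were 2 libraries each for dPC12EVs, uPC12EVs and PBS, and all sample columns were assigned from the labels. The processing notes name STAR 2.7.8a and the build mm10, which is a mouse build, while the rows are rat genes. The counting tool, the annotation and the normalizing tool are not given in the sources used here. The deposited columns headed raw hold expected counts, estimated reads per gene that are not scaled. Over all 36865 genes, those at 0 included, 27.1% to 28.0% of the values per library are fractional. The deposited columns headed normalized hold log2 values of transcript levels (TPM), with values under a TPM of 1 set to 1. The deposited fold changes are differences between group means of those log2 values, with no test. The deposited sheet of genes lower with uPC12EVs than with PBS repeats the 23 higher genes, so the 24 lower genes at a fold of 1.5 were taken from the table of all genes. The start of the 27825 genes found in the RefSeq table matched in 0 of them, so no positions are given.

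The expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (9518 of 36865), normalized by TMM and fitted with glmQLFit on the 3 groups over all 6 libraries, which leaves 3 residual degrees of freedom. Each comparison was tested with glmQLFTest, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The SE of a fold change is its size divided by the square root of the F statistic. CPM are counts scaled to the library size over the genes kept, adjusted by the TMM factor. Sums of marker counts are set against the library totals, which run from 13742679 to 20635111. Intervals of counts cover counting error only, with a confidence level of 95% (exact binomial), and intervals of medians are over genes. The common biological coefficient of variation was 2.09%.

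A total of 42 gene lists was fixed before the data were examined, and the 34 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. The lists were tested again with an estimated correlation and with fry, with adjustment within each comparison. With an estimated correlation camera has only the 3 residual degrees of freedom, so a list can fail there without correlation between its genes. For hypoxia genes in dPC12EVs against PBS the estimated correlation was -0.034, under the preset value, and the list still failed (adjusted p = 0.106 by camera). Of 945 genes in the lists, 890 were found by symbol, 6 by an alias, 24 through the RefSeq table, and 25 were not matched. The genes to name were set by a rule before the data were examined. They are up to 10 genes higher and 10 lower per comparison, by size of change among those called, at a mean of 5 CPM or more and without overlap between the groups; places left over went to genes that did not pass. Added to these are up to 4 members of each list called by camera and 12 genes chosen for the question, among them Adrb2, Vegfa, Il6, Ngf, Vim and Th. Not all genes of the rule and not all called lists are described. Genes outside the rule, such as Timp2, Epgn and Cnfn, were picked after their values were seen and were not followed under the alternatives. Th had from 2 to 7 counts per library and was not tested.

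The alternatives were DESeq2 size factors (RLE), no filter on low counts, a mean of at least 5 CPM, the 4 libraries compared alone, replicate number as a block, each library left out in turn, DESeq2 1.42.0 in place of edgeR (its default filter on mean counts leaves some genes without an adjusted p), and an adjusted p under 0.10. After the data were seen a correction for transcript length (a loess trend per library with a span of 0.5 on the length implied by the deposited values) and a glmTreat test against a fold of 1.1 were added. The test of dPC12EVs against PBS was tested on simulated data with 200 changed genes; it recovered 16% of the changes of 1.1-fold, 80% of 1.2-fold, 98% of 1.5-fold and 100% of 2-fold, with 9 unchanged genes called of 9489 tested. Overlap and covariance were set against 50 simulations in which neither kind of EV had an effect. Tables were handled with the R package data.table (1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.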

Results

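The libraries came from RMT1, a rat breast cancer cell line. The cells were treated with extracellular vesicles (EVs), membrane particles that cells release, from PC12, a rat pheochromocytoma line that takes on traits of sympathetic neurons when given nerve growth factor. The groups were EVs of differentiated PC12 cells (dPC12EVs), EVs of undifferentiated PC12 cells (uPC12EVs) and the vehicle, phosphate-buffered saline (PBS), with 2 libraries each. The counts summed to 13742679 and 16858331 in the PBS libraries, 15538057 and 15792516 in the uPC12EVs libraries, and 15063843 and 20635111 in the dPC12EVs libraries. After the filter on low counts 9518 genes were tested. Levels are given as counts scaled to the normalized library size (CPM), as mean ± SD (n = 2), and fold changes on the log2 scale with their SE. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples. Positions are left out because the genome build of the deposited coordinates could not be settled. Features of the mitochondrial genome were listed at 0 in all 6 libraries, so mitochondrial transcripts were not assessed.

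The comparison of dPC12EVs against PBS asked what EVs of neuron-like PC12 cells do to gene expression in the cancer cells. Mmp13, a collagenase (Entrez gene 171052), fell by 65.7%, from 18.1 ± 1.58 to 6.19 ± 0.483 CPM (log2 fold change -1.54, SE 0.12, adjusted p = 1.01e-11). Mmp9, a gelatinase (81687), fell by 47.2% (log2 fold change -0.92, SE 0.11, adjusted p = 6.78e-07), and Mmp3, a stromelysin (171045), fell by 25.7% (log2 fold change -0.43, SE 0.06, adjusted p = 1.43e-05). Serpine1, the inhibitor of plasminogen activators (24617), went from 77.3 ± 1.4 to 51 ± 0.0394 CPM (log2 fold change -0.60, SE 0.048, adjusted p = 4.1e-11), and Vegfa, the angiogenic growth factor (83785), from 134 ± 4.63 to 95.3 ± 4.13 (log2 fold change -0.49, SE 0.044, adjusted p = 6.16e-10). Vim, the intermediate filament protein of mesenchymal cells (81818), rose by 42.9%, from 751 ± 33.2 to 1073 ± 5.51 CPM (log2 fold change 0.52, SE 0.031, adjusted p = 2.09e-14). Amotl2, a junction protein of the angiomotin family and a target of YAP (65157), rose from 128 ± 3.15 to 176 ± 0.918 (log2 fold change 0.46, SE 0.039, adjusted p = 2.41e-10). Among epithelial genes, Krt8, a keratin of simple epithelia (25626), fell from 51.9 ± 3.95 to 37.3 ± 3.95 (log2 fold change -0.48, SE 0.065, adjusted p = 6.36e-06), and the adhesion molecule Epcam and the tight junction protein Cldn4 had log2 fold changes of -0.19 and -0.27 (SE 0.034 and 0.045). Each gene named so far stayed called without each of the 6 libraries in turn, and DESeq2 gave no adjusted p for Mmp13 and Mmp9. Of the 18 epithelial members measured, 0 rose, these 3 fell and 15 did not pass, against 0 and 3 adjusted over the list alone. Fold changes were positive in 8 and negative in 10, with a median of -0.0097 (adjusted p = 0.0368 by camera and adjusted p = 0.207 with an estimated correlation). The list call was lost without PBS replicate 2 (median -0.018, adjusted p = 0.0768) and without dPC12EVs replicate 2 (median -0.016, adjusted p = 0.131), and without dPC12EVs replicate 1 the median was -0.019. It was also lost with no filter on low counts, with a mean of at least 5 CPM and after a correction for transcript length chosen after seeing the data (adjusted p = 0.156, 0.0605 and 0.0502 in dPC12EVs against PBS).

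Groups of genes were fixed before the data were examined. Of the proteases of invasion, 1 of 19 measured members rose, 5 fell and 13 did not pass, against 1 and 7 adjusted over the list alone. Besides the matrix metalloproteinases above, Plau, the urokinase, fell (log2 fold change -0.23, SE 0.042, adjusted p = 0.000699), and the member that rose was Timp2, an inhibitor of these proteases (0.16, SE 0.047). The group was lower as a whole (adjusted p = 2.57e-09 by camera and adjusted p = 0.106 with an estimated correlation). Growth factor and ERK feedback genes were lower (adjusted p = 1.87e-05 by camera and adjusted p = 0.207 with an estimated correlation). Among 18 measured members, 1 rose, 6 fell and 11 did not pass, against 1 and 9 adjusted over the list alone. Those that fell included Fosl1, Dusp6, Phlda1 and Tgfa, at log2 fold changes of -0.25, -0.18, -0.19 and -0.18 (SE 0.057, 0.044, 0.043 and 0.04), and the growth factor Epgn (0.22, SE 0.05) rose. Immediate early genes were lower (adjusted p = 1.82e-05 by camera and adjusted p = 0.106 with an estimated correlation). Of the 18 members measured, 1 rose, 5 fell and 12 did not pass, against 1 and 7 adjusted over the list alone. Lower members included Jun (-0.21, SE 0.042), Ier2 (-0.21, SE 0.043) and Ier3 (-0.24, SE 0.045), and Cyr61 was higher. Inflammatory NF-kB targets were lower (adjusted p = 5.73e-08 by camera and adjusted p = 0.185 with an estimated correlation). Of 18 measured members, 0 rose, 6 fell and 12 did not pass, against 0 and 9 adjusted over the list alone. Members called included the chemokine Ccl2 (-0.52, SE 0.075), the NF-kB inhibitor Nfkbia (-0.34, SE 0.06) and the cyclooxygenase Ptgs2 (-0.21, SE 0.044). Calls ended without PBS replicate 1 for Fosl1 and Jun, and without PBS replicate 2 for Ccl2, Dusp6, Fosl1, Ier2, Nfkbia, Phlda1, Plau, Ptgs2 and Tgfa. Calls also ended without dPC12EVs replicate 1 for Dusp6, Ier2, Phlda1, Ptgs2 and Tgfa (adjusted p from 0.0547 to 0.515 over these). Among these calls, log2 fold changes that moved by more than 1.5 times were Dusp6 -0.11 without PBS replicate 2, Tgfa -0.11 without PBS replicate 2, Ccl2 -0.33 without PBS replicate 2. Other settings that ended calls were the fit with DESeq2 for Dusp6, Fosl1, Ier2, Nfkbia, Phlda1, Ptgs2 and Tgfa (adjusted p from 0.067 to 0.308).

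Hypoxia genes were lower (adjusted p = 2.04e-08 by camera and adjusted p = 0.106 with an estimated correlation). Among 18 measured members, 0 rose, 3 fell and 15 did not pass, against 0 and 5 adjusted over the list alone. Among those called were Ndrg1 (-0.31, SE 0.032), Vegfa and the glucose transporter Slc2a1 (-0.11, SE 0.029). Targets of YAP and TAZ were higher, with positive fold changes in 12 of 12 members (adjusted p = 8.02e-09 by camera and adjusted p = 0.106 with an estimated correlation). Of the 12 members measured, 4 rose, 0 fell and 8 did not pass, against 6 and 0 adjusted over the list alone. They included Amotl2, the matricellular gene Cyr61 (0.73, SE 0.19) and Gadd45b (0.27, SE 0.062). Mesenchymal genes were higher (adjusted p = 0.00248 by camera and adjusted p = 0.162 with an estimated correlation). Of 14 measured members, 4 rose, 1 fell and 9 did not pass, against 4 and 1 adjusted over the list alone. Vim rose together with the matrix genes Sparc, Loxl2 and Fn1, whose log2 fold changes were 0.15, 0.22 and 0.12 (SE 0.028, 0.051 and 0.032), and the member that fell was Mmp9. For dPC12EVs against PBS this list call was lost without PBS replicate 1 (median 0.056 against 0.091, adjusted p = 0.187) and with no filter on low counts (adjusted p = 0.133). The summed counts of 13 fibroblast markers, some of them matrix genes, were 1.06 times those in PBS (95% interval 0.982 to 1.15). Mitotic genes were higher (adjusted p = 2.79e-07 by camera and adjusted p = 0.185 with an estimated correlation). Among 28 measured members, 2 rose, 0 fell and 26 did not pass, against 3 and 0 adjusted over the list alone. The members called included the proliferation marker Mki67 (0.14, SE 0.028) and the cyclin Ccna2 (0.15, SE 0.039). Nucleolar MYC targets were higher (adjusted p = 2.79e-07 by camera and adjusted p = 0.185 with an estimated correlation). Of the 28 members measured, 4 rose, 0 fell and 24 did not pass, against 9 and 0 adjusted over the list alone. Members called included nucleolin, Ncl (0.15, SE 0.03). Calls ended without PBS replicate 1 for Ccna2, Cyr61, Fn1, Loxl2, Mki67, Ncl, Slc2a1 and Sparc, and without PBS replicate 2 for Ccna2, Cyr61, Fn1, Gadd45b, Loxl2, Mki67, Ncl and Slc2a1. Calls also ended without dPC12EVs replicate 1 for Ccna2, Fn1, Loxl2, Ncl and Slc2a1, and without dPC12EVs replicate 2 for Ccna2, Cyr61, Fn1, Gadd45b, Loxl2, Mki67 and Slc2a1 (adjusted p from 0.0503 to 0.446 over these). Other settings that ended calls were the fit with DESeq2 for Ccna2, Fn1, Gadd45b, Loxl2 and Slc2a1 (adjusted p from 0.0776 to 0.22). DESeq2 gave no adjusted p for Cyr61.

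Genes of EV and endosome machinery were lower (adjusted p = 0.000272 by camera and adjusted p = 0.125 with an estimated correlation). Of 24 measured members, 0 rose, 5 fell and 19 did not pass, against 0 and 7 adjusted over the list alone. Among those called were the tetraspanins Cd9 (-0.17, SE 0.03) and Cd81 (-0.15, SE 0.031). Lysosomal genes were lower (adjusted p = 0.00248 by camera and adjusted p = 0.162 with an estimated correlation). Among 25 measured members, 0 rose, 2 fell and 23 did not pass, against 0 and 4 adjusted over the list alone. The members called included the cathepsin Ctsl (-0.13, SE 0.03) and the autophagy receptor Sqstm1 (-0.12, SE 0.031). Replication genes of S phase were higher by the list test although 0 of 29 members passed, over all genes or adjusted over the list alone (adjusted p = 1.87e-05 by camera and adjusted p = 0.106 with an estimated correlation). Median log2 fold changes over list members were -0.031 for EV machinery, -0.047 for lysosomal, -0.077 for hypoxia and -0.058 for invasion genes. They were 0.069 for S phase, 0.066 for nucleolar MYC, 0.073 for mitotic and 0.091 for mesenchymal genes. YAP and TAZ targets had 0.11, ERK feedback genes -0.15, and immediate early and NF-kB genes -0.16 each. Outside these groups, Ncam1 (0.41, SE 0.081), a neural cell adhesion molecule, Atp1b1 (0.42, SE 0.061), a subunit of the sodium pump, and Abcg1 (0.55, SE 0.13), a cholesterol exporter, rose. Pthlh, the parathyroid hormone-like hormone, and Niacr1, the niacin receptor, fell (-0.76, SE 0.17, and -0.50, SE 0.083). Of the genes named in advance, the beta-adrenergic receptor Adrb2 (-0.17, SE 0.19), Fos (-0.014, SE 0.14), Myc (0.041, SE 0.042), Cdh1 (0.055, SE 0.035), Il6 (0.061, SE 0.32), Egr1 (-0.24, SE 0.092) and Ngf (-0.12, SE 0.17) did not pass, and Hmgcr, the rate-limiting enzyme of cholesterol synthesis, fell (log2 fold change -0.12, SE 0.031, adjusted p = 0.0297). Among the genes that did not pass, leaving out 1 library in turn gave log2 fold changes of -0.27 to -0.074 for Adrb2, -0.24 to 0.13 for Fos, -0.012 to 0.1 for Myc, 0.0051 to 0.11 for Cdh1, -0.28 to 0.42 for Il6, -0.40 to -0.037 for Egr1 and -0.19 to -0.042 for Ngf. Calls ended without PBS replicate 1 for Ctsl, Hmgcr, Ncam1 and Sqstm1, and without PBS replicate 2 for Abcg1, Cd81, Cd9, Ctsl, Hmgcr, Niacr1, Pthlh and Sqstm1. Calls also ended without dPC12EVs replicate 1 for Ctsl, Hmgcr, Pthlh and Sqstm1, and without dPC12EVs replicate 2 for Cd9, Ctsl, Hmgcr and Sqstm1 (adjusted p from 0.0503 to 0.702 over these). Among these calls, log2 fold changes that moved by more than 1.5 times were Abcg1 0.99 without PBS replicate 1 and 0.16 without PBS replicate 2. Other settings that ended calls were the fit with DESeq2 for Hmgcr and Sqstm1 (adjusted p from 0.164 to 0.174). DESeq2 gave no adjusted p for Abcg1, Ncam1, Niacr1 and Pthlh.

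In total 260 genes differed between dPC12EVs and PBS, 106 higher and 154 lower, with a median fold of 1.14; 15 of them changed by more than 1.5-fold. At an unadjusted p under 0.05 the number was 1383. The camera test called 16 of 34 lists, 5 higher and 11 lower, with median, mean and test of the same sign in each. No list stayed called with an estimated correlation, a test with few degrees of freedom, and 8 of the 16 passed with fry. These were the invasion, hypoxia, YAP and TAZ, immediate early, S phase, lysosomal, EV machinery and epithelial lists. Their adjusted p by fry lay between 0.0256 and 0.0431. The ERK feedback, NF-kB, mesenchymal, mitotic and nucleolar MYC lists were among those that did not pass with fry (adjusted p from 0.0770 to 0.107). The number of genes called was 94 without PBS replicate 1, 57 without PBS replicate 2, 454 without uPC12EVs replicate 1, 457 without uPC12EVs replicate 2, 139 without dPC12EVs replicate 1 and 125 without dPC12EVs replicate 2. The spread within groups was largest with uPC12EVs, at a chi-square per degree of freedom of 2.35 against 1.37 with PBS. DESeq2, whose filter on mean counts leaves genes without an adjusted p, called 78 genes, and a test against a fold of 1.1, chosen after seeing the data, called 24.

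**Figure D1:**
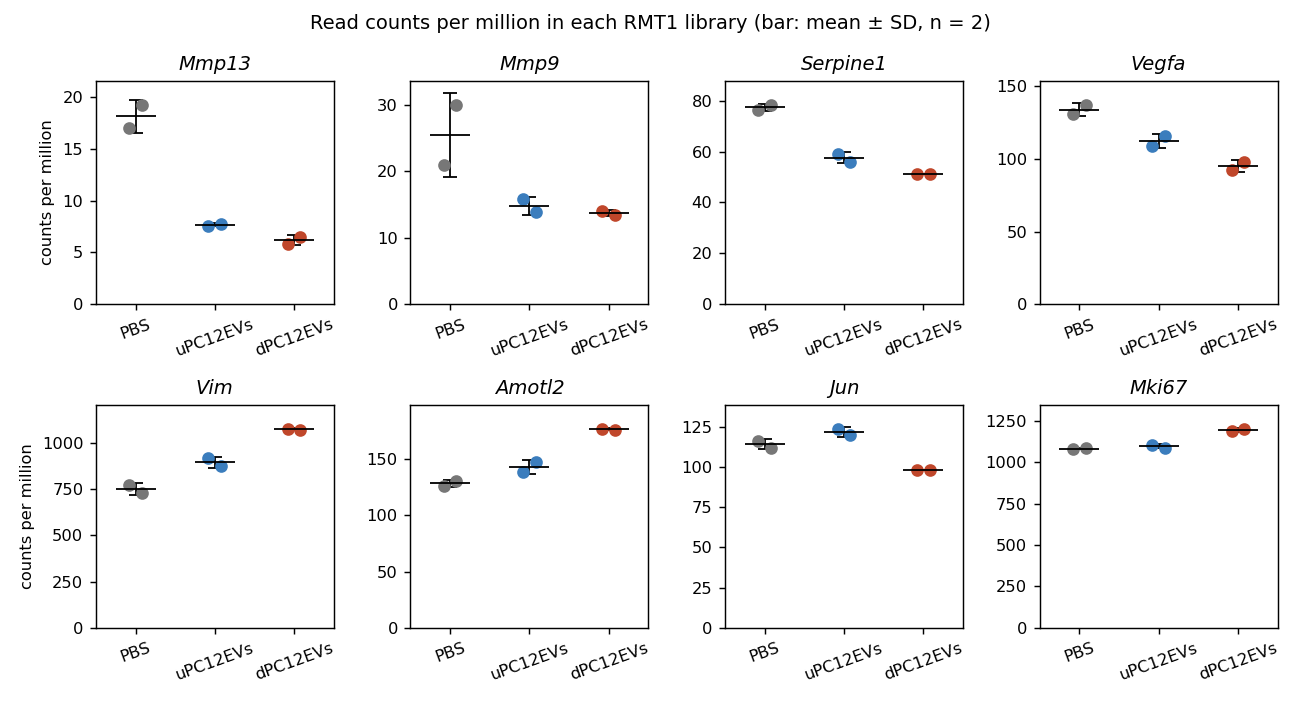
CPM (vertical axis, from 0) of 8 genes in the 6 libraries; points are libraries, the long bar is the group mean and the whiskers are ± SD (n = 2). The dPC12EVs libraries lie below both PBS libraries for Mmp13, Mmp9, Serpine1, Vegfa and Jun and above them for Vim, Amotl2 and Mki67.

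The comparison of dPC12EVs against uPC12EVs asked whether EVs of differentiated cells act differently from those of undifferentiated cells. Vim was 19.9% higher with dPC12EVs, at 1073 ± 5.51 against 895 ± 29.4 CPM (log2 fold change 0.26, SE 0.031, adjusted p = 3.94e-06). Thbs1, the matrix glycoprotein thrombospondin (445442), was 636 ± 6.52 against 528 ± 36.2 (log2 fold change 0.27, SE 0.034, adjusted p = 8.99e-06), and Fn1, fibronectin (25661), and Amotl2 were also higher (log2 fold changes 0.19 and 0.30, SE 0.032 and 0.039). Lower with dPC12EVs were Jun (24516) and Jund (24518), transcription factors of the activator protein family: Jun went from 122 ± 3 to 98.3 ± 0.176 CPM (log2 fold change -0.31, SE 0.042, adjusted p = 1.88e-05) and Jund from 25.7 ± 2.08 to 18 ± 1.11 (log2 fold change -0.52, SE 0.082, adjusted p = 0.000271). Lgals7, a galectin of stratified epithelia (29518), went from 131 ± 4.08 to 102 ± 4.57 (log2 fold change -0.36, SE 0.046, adjusted p = 8.99e-06), and the epidermal fatty acid binding protein Fabp5 (140868) fell by 19.2% (log2 fold change -0.31, SE 0.048). The stress response gene Ndrg1 (299923) fell by 14.3% (log2 fold change -0.22, SE 0.032). Each gene of this paragraph stayed called without each of the 6 libraries in turn, and DESeq2 gave no adjusted p for Amotl2, Fabp5, Jun, Jund and Lgals7.

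Immediate early genes were lower with dPC12EVs (adjusted p = 6.99e-06 by camera and adjusted p = 0.178 with an estimated correlation). Of the 18 members measured, 0 rose, 4 fell and 14 did not pass, against 0 and 6 adjusted over the list alone. Members called included Jun, Ier3 (-0.19, SE 0.045), Ier2 (-0.17, SE 0.043) and Junb (-0.16, SE 0.04). Targets of YAP and TAZ were higher (adjusted p = 5.22e-07 by camera and adjusted p = 0.178 with an estimated correlation). Of 12 measured members, 2 rose, 0 fell and 10 did not pass, against 5 and 0 adjusted over the list alone. Among those called were Amotl2 and Gadd45b (0.27, SE 0.062). Mesenchymal genes were higher by the list test, with 7 positive and 7 negative members (adjusted p = 0.00151 by camera and adjusted p = 0.219 with an estimated correlation). Among 14 measured members, 4 rose, 0 fell and 10 did not pass, against 4 and 0 adjusted over the list alone. Those that rose were Vim, Fn1, Loxl2 (0.19, SE 0.051) and the collagen Col1a1 (0.37, SE 0.072), and the summed fibroblast markers, a list that holds Col1a1, were 0.839 times the PBS level with uPC12EVs (95% interval 0.769 to 0.916). The median of the mesenchymal list was 0.013 for dPC12EVs against uPC12EVs, -0.012 without uPC12EVs replicate 1, 0.038 without uPC12EVs replicate 2 and 0.041 without dPC12EVs replicate 2. Lysosomal genes were lower by the list test, with negative fold changes in 24 of 25 members (adjusted p = 9.6e-08 by camera and adjusted p = 0.178 with an estimated correlation). Of the 25 members measured, 0 rose, 2 fell and 23 did not pass, against 0 and 7 adjusted over the list alone. The members called included Sqstm1 (-0.13, SE 0.031) and the proton pump subunit Atp6v1h (-0.22, SE 0.056). Mitotic genes were higher (adjusted p = 5.07e-07 by camera and adjusted p = 0.238 with an estimated correlation). Of 28 measured members, 2 rose, 0 fell and 26 did not pass, against 6 and 0 adjusted over the list alone. Members called included Mki67 (0.12, SE 0.028) and Cenpf (0.12, SE 0.032). Hypoxia genes were lower (adjusted p = 0.0102 by camera and adjusted p = 0.238 with an estimated correlation). Among 18 measured members, 0 rose, 2 fell and 16 did not pass, against 0 and 3 adjusted over the list alone. Among those called were Ndrg1 and Vegfa (-0.24, SE 0.045). That list call was lost without dPC12EVs replicate 1, with a median of -0.047 against -0.048 in all libraries. NF-kB targets were lower (adjusted p = 0.00744 by camera and adjusted p = 0.487 with an estimated correlation). Of the 18 members measured, 0 rose, 2 fell and 16 did not pass, against 0 and 2 adjusted over the list alone. The members called included Ccl2 (-0.32, SE 0.076) and Nfkbia (-0.25, SE 0.061). For dPC12EVs against uPC12EVs that list call was lost without uPC12EVs replicate 2 (adjusted p = 0.737) and with no filter on low counts (adjusted p = 0.0575). Calls ended without PBS replicate 1 for Atp6v1h, Cenpf, Ier2, Junb, Loxl2 and Sqstm1, and without PBS replicate 2 for Atp6v1h, Cenpf, Ier2, Junb, Loxl2 and Sqstm1. Calls also ended without dPC12EVs replicate 1 for Cenpf, Gadd45b, Ier2, Junb, Loxl2, Mki67, Sqstm1 and Vegfa, and without dPC12EVs replicate 2 for Atp6v1h, Ccl2, Col1a1, Gadd45b, Ier2, Ier3, Loxl2, Mki67, Nfkbia and Sqstm1. Further calls ended without uPC12EVs replicate 1 for Ier2, and without uPC12EVs replicate 2 for Atp6v1h, Ccl2, Cenpf, Col1a1, Gadd45b, Ier3, Junb, Loxl2, Nfkbia and Sqstm1 (adjusted p from 0.0514 to 0.556 over these). Among these calls, log2 fold changes that moved by more than 1.5 times were Col1a1 0.24 without uPC12EVs replicate 2, Loxl2 0.11 without uPC12EVs replicate 2, Junb -0.083 without dPC12EVs replicate 1 and -0.25 without dPC12EVs replicate 2, Atp6v1h -0.13 without dPC12EVs replicate 2, Nfkbia -0.38 without uPC12EVs replicate 1 and -0.11 without uPC12EVs replicate 2. After the correction for transcript length, chosen after seeing the data, the calls of Mki67 (0.079, adjusted p = 0.0626) and Cenpf (0.077, adjusted p = 0.216) ended. Other settings that ended calls were the fit with only the 4 libraries compared for Atp6v1h, Cenpf, Gadd45b, Ier2, Ier3, Junb, Loxl2, Mki67, Nfkbia and Sqstm1, and the fit with DESeq2 for Cenpf and Junb (adjusted p from 0.05 to 0.369). DESeq2 gave no adjusted p for Atp6v1h, Ccl2, Col1a1, Gadd45b, Ier2, Ier3, Loxl2, Nfkbia and Vegfa.

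Ribosomal protein genes were lower by the list test, with negative fold changes in 35 of 37 members, a median of -0.044 and no member past the threshold, over all genes or adjusted over the list alone (adjusted p = 1.58e-05 by camera and adjusted p = 0.693 with an estimated correlation). Without uPC12EVs replicate 2 the median was 0.0057 (adjusted p = 0.416), without uPC12EVs replicate 1 it was -0.09, and without dPC12EVs replicate 2 it was -0.025 (adjusted p = 0.0636). These genes are short, and fold changes rose with transcript length across genes here (Spearman's rho 0.222, over 5504 genes, which are not independent replicates). A separate rho was taken between transcript length and the deviation of each library from the mean of the others. It was -0.467 in uPC12EVs replicate 2 and between 0.0147 and 0.177 in the other libraries, whose reference includes uPC12EVs replicate 2. Outside the groups, Sprr1a, a protein of the cornified envelope, and Spink5, a protease inhibitor of the epidermis, fell (-0.54, SE 0.12, and -0.41, SE 0.10). Plcxd2, the semaphorin Sema3e, Ncam1 and Atp1b1 rose, at log2 fold changes of 0.57, 0.42, 0.36 and 0.26 (SE 0.13, 0.11, 0.08 and 0.059). Among the genes named in advance, Adrb2 (0.036, SE 0.20), Fos (-0.055, SE 0.14), Myc (0.018, SE 0.042), Cdh1 (0.034, SE 0.035), Il6 (0.056, SE 0.32), Egr1 (-0.083, SE 0.094), Ngf (-0.17, SE 0.17) and Hmgcr (-0.073, SE 0.031) did not pass. For these, leaving out 1 library in turn gave log2 fold changes of -0.086 to 0.17 for Adrb2, -0.27 to 0.093 for Fos, -0.0038 to 0.041 for Myc, -0.0017 to 0.073 for Cdh1, -0.24 to 0.38 for Il6 and -0.13 to -0.033 for Egr1. Calls ended without PBS replicate 1 for Sema3e and Spink5, and without PBS replicate 2 for Sema3e and Spink5. Calls also ended without dPC12EVs replicate 1 for Atp1b1, Plcxd2, Sema3e and Spink5, and without dPC12EVs replicate 2 for Ncam1 and Spink5. Further calls ended without uPC12EVs replicate 1 for Plcxd2 and Sema3e, and without uPC12EVs replicate 2 for Atp1b1, Ncam1, Sema3e, Spink5 and Sprr1a (adjusted p from 0.0537 to 0.606 over these). Among these calls, log2 fold changes that moved by more than 1.5 times were Sprr1a -0.84 without uPC12EVs replicate 1 and -0.15 without uPC12EVs replicate 2, Spink5 -0.21 without uPC12EVs replicate 2, Atp1b1 0.16 without uPC12EVs replicate 2. Other settings that ended calls were the fit with only the 4 libraries compared for Plcxd2, Sema3e and Spink5 (adjusted p from 0.054 to 0.0663). DESeq2 gave no adjusted p for Atp1b1, Ncam1, Plcxd2, Sema3e, Spink5 and Sprr1a.

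In total 105 genes differed between dPC12EVs and uPC12EVs, 40 higher and 65 lower, with a median fold of 1.16. Of them, 2 changed by more than 1.5-fold, and 1214 genes had an unadjusted p under 0.05. With only the 4 libraries compared, 37 were called. The uPC12EVs libraries differed from each other by a chi-square per degree of freedom of 2.35. Against the dPC12EVs libraries it was 2.43 and 2.30 for uPC12EVs replicate 1, and 2.74 and 3.36 for replicate 2. The 3 groups share 1 estimate of the spread per gene, so the calls may rest on too small a spread for uPC12EVs. The camera test called 12 of 34 lists, 5 higher and 7 lower, and none stayed called with an estimated correlation or with fry. In DESeq2 a filter on mean counts left genes without an adjusted p, and those could not be called. The number of genes called was 45 without PBS replicate 1, 47 without PBS replicate 2, 220 without uPC12EVs replicate 1, 56 without dPC12EVs replicate 1 and 47 without dPC12EVs replicate 2. Without uPC12EVs replicate 2 it was 97, of which 48 were among the 105, and DESeq2 called 29.

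**Figure D2:**
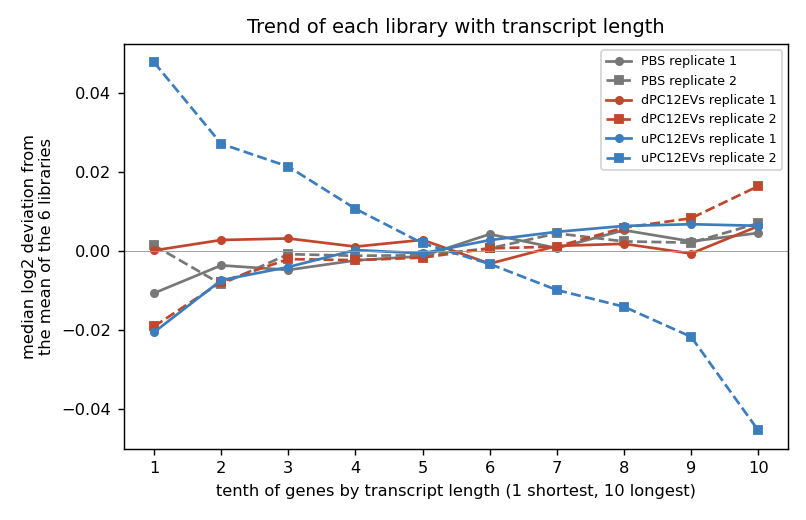
Median log2 deviation of each library from the mean of the 6 libraries (vertical axis) in bins of genes ordered by transcript length (horizontal axis, shortest at the left); each line is 1 library. The line of uPC12EVs replicate 2 falls from the shortest to the longest genes. Its deviation from the mean of the other libraries had a rho of -0.467 with length across genes.

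The comparison of uPC12EVs against PBS asked what EVs of undifferentiated PC12 cells do. Mmp13 fell by 57.8%, to 7.68 ± 0.126 CPM (log2 fold change -1.25, SE 0.11, adjusted p = 6.88e-09), and Mmp3 went from 51.9 ± 3.15 to 38.3 ± 3.17 (log2 fold change -0.44, SE 0.062, adjusted p = 3.63e-05). Serpine1 fell to 57.5 ± 2.18 (log2 fold change -0.43, SE 0.048, adjusted p = 6.37e-07), and Vim rose from 751 ± 33.2 to 895 ± 29.4 (log2 fold change 0.25, SE 0.031, adjusted p = 4.22e-06); the calls of these 4 genes held without each of the 6 libraries in turn. Also lower were Mmp9 (-0.81, SE 0.11), Vegfa (-0.25, SE 0.044), the growth factor Tgfa (-0.22, SE 0.041), the caspase Casp3 (-0.27, SE 0.046), the endocytic gene Ehd3 (-0.24, SE 0.049) and the autophagy gene Atg9b (-0.33, SE 0.058). Higher were Fabp5 (0.27, SE 0.049), the keratins Krt16 (0.17, SE 0.036) and Krt17 (0.14, SE 0.03), the stress-induced transcription factor Atf5 (0.18, SE 0.033), the growth arrest gene Gas6 (0.19, SE 0.035) and Scrn1 (0.22, SE 0.05). Calls ended without PBS replicate 1 for Atf5, Atg9b, Fabp5, Gas6, Krt16 and Krt17, and without PBS replicate 2 for Casp3, Ehd3, Gas6, Krt17, Mmp9, Scrn1, Tgfa and Vegfa. Calls also ended without uPC12EVs replicate 2 for Atf5, Fabp5, Krt16, Krt17 and Scrn1 (adjusted p from 0.0707 to 0.788 over these). Among these calls, log2 fold changes that moved by more than 1.5 times were Mmp9 -0.51 without PBS replicate 2, Krt16 0.11 without PBS replicate 1 and 0.085 without uPC12EVs replicate 2, Ehd3 -0.14 without PBS replicate 2, Scrn1 0.13 without PBS replicate 2. Other settings that ended calls were the fit with DESeq2 for Atf5, Atg9b, Casp3, Ehd3, Fabp5, Gas6, Krt16, Krt17, Mmp9, Scrn1, Tgfa and Vegfa (adjusted p from 0.059 to 1).

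Invasion proteases were lower (adjusted p = 4.54e-08 by camera and adjusted p = 0.242 with an estimated correlation). Of 19 measured members, 0 rose, 3 fell and 16 did not pass, against 1 and 5 adjusted over the list alone. Mmp10, a stromelysin, did not pass (-0.56, SE 0.14). ERK feedback genes were lower (adjusted p = 6.07e-05 by camera and adjusted p = 0.291 with an estimated correlation). Among 18 measured members, 0 rose, 1 fell and 17 did not pass, against 1 and 4 adjusted over the list alone. Tgfa was the member called, and Fosl1 (-0.25, SE 0.059) and Etv4 (-0.19, SE 0.05) did not pass. TGF-beta targets were lower (adjusted p = 0.000337 by camera and adjusted p = 0.291 with an estimated correlation). Of the 17 members measured, 0 rose, 1 fell and 16 did not pass, against 0 and 2 adjusted over the list alone. Serpine1 was the member called, and Col1a1 (-0.27, SE 0.075) did not pass. The fibroblast marker ratio of 0.839 includes Col1a1, so the 2 values are not separate. Besides Col1a1, only Pdgfra of those markers passed the filter on low counts. Hypoxia genes were lower (adjusted p = 0.000337 by camera and adjusted p = 0.291 with an estimated correlation). Of 18 measured members, 0 rose, 1 fell and 17 did not pass, against 0 and 5 adjusted over the list alone. Vegfa was the member called. Ribosomal protein genes were higher by the list test with no member past the threshold, over all genes or adjusted over the list alone (adjusted p = 0.000634 by camera and adjusted p = 0.871 with an estimated correlation), beside a rho of -0.235 between fold change and transcript length. Their median was 0.03, and -0.022 without uPC12EVs replicate 2 (adjusted p = 0.00796). Without uPC12EVs replicate 1 it was 0.081, and without PBS replicate 2 it was 0.052. The call was lost without PBS replicate 1 (median 0.016, adjusted p = 0.241). For uPC12EVs against PBS it was also lost after the correction for transcript length, with a median of 0.01 (adjusted p = 0.229). The genes Adrb2 (-0.21, SE 0.20), Fos (0.041, SE 0.14), Myc (0.023, SE 0.042), Cdh1 (0.021, SE 0.036), Il6 (0.0047, SE 0.33), Egr1 (-0.16, SE 0.094), Ngf (0.049, SE 0.17), Mki67 (0.019, SE 0.028) and Hmgcr (-0.045, SE 0.031) did not pass. Leaving out 1 library in turn, values that did not pass ran over -0.37 to -0.14 for Fosl1, -0.42 to -0.14 for Col1a1, -0.34 to -0.086 for Adrb2, -0.035 to 0.11 for Fos, -0.03 to 0.082 for Myc, -0.029 to 0.076 for Cdh1, -0.33 to 0.36 for Il6, -0.31 to 0.046 for Egr1, -0.018 to 0.13 for Ngf and 0.0062 to 0.029 for Mki67.

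In total 20 genes differed between uPC12EVs and PBS, 8 higher and 12 lower, with a median fold of 1.19. Of them, 3 changed by more than 1.5-fold, and 778 genes had an unadjusted p under 0.05. With only the 4 libraries compared, 48 were called. The chi-square per degree of freedom was 2.35 between the uPC12EVs libraries. Against the PBS libraries it was lower for uPC12EVs replicate 1 (1.78 and 1.85) and higher for replicate 2 (2.61 and 2.46). The camera test called 15 of 34 lists, 7 higher and 8 lower, and none stayed called with an estimated correlation or with fry. The number of genes called was 11 without PBS replicate 1, 10 without PBS replicate 2, 96 without uPC12EVs replicate 1, 37 without dPC12EVs replicate 1 and 38 without dPC12EVs replicate 2. DESeq2 called 4 genes.

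Both EV comparisons used the same PBS libraries, so their fold changes share the error of those libraries. Of the genes called against PBS, 13 were shared: Gas6, Scrn1 and Vim were higher with both kinds of EV, and Mmp13, Mmp9, Mmp3, Serpine1, Vegfa, Tgfa, Casp3, Ehd3, Atg9b and Cacna1i were lower. Independent calls would have shared 0.0891 higher and 0.194 lower, values that leave out the shared PBS error. In 50 simulations with no effect at most 1 was shared, but such data give few calls that could be shared. The overlap that the shared PBS libraries would give beside an effect of dPC12EVs alone was not counted. How much of the overlap they account for therefore stays open. The number shared was 5 without PBS replicate 2, 39 without uPC12EVs replicate 1 and 3 with DESeq2. The covariance of the fold changes across 8391 genes was 0.00451, against 0.00291 (SD 8.93e-05) in the simulations. With 1 shared PBS library the simulated values rose too: without PBS replicate 1 it was 0.00703 against 0.00538 (SD 0.000142), and without PBS replicate 2 it was 0.00749 against 0.00637 (SD 0.000134). The correlation across genes was 0.530, within the simulated values, the highest of which was 0.546, and genes are not independent replicates. The PBS libraries could not be divided into separate controls with 2 libraries for each comparison.

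**Figure D3:**
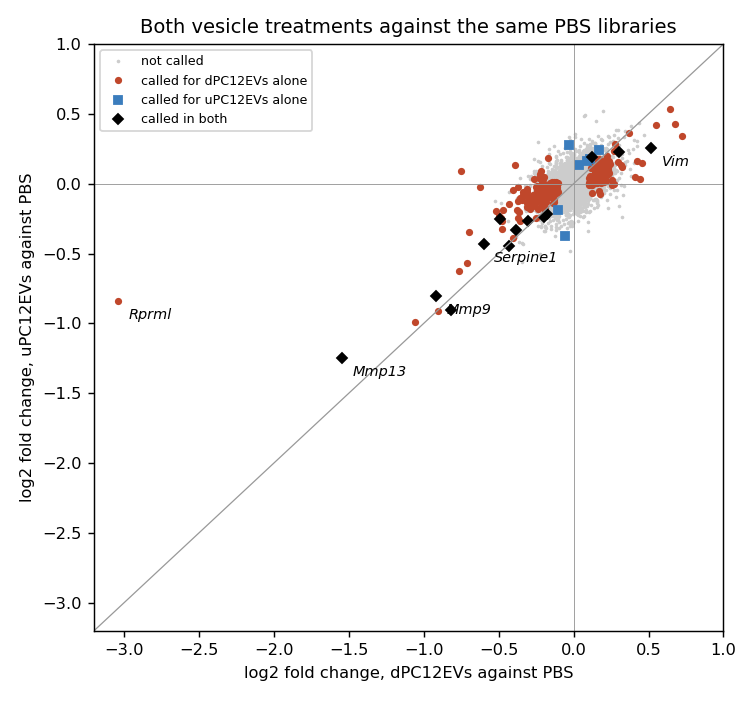
Log2 fold change of each gene against PBS with dPC12EVs (horizontal axis) and with uPC12EVs (vertical axis); grey points are genes at 5 CPM or more that were not called, and the line marks equal change. The 13 genes called in both lie at the lower left and the upper right. Rprml, at the far left, had 18 and 19 counts with PBS and 2 and 3 with dPC12EVs, and is labelled because of its place in the plot.

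The deposited workbook lists genes at a fold of 1.5 or more without a test. Of 54 such genes for dPC12EVs against PBS, 41 were tested here and 12 were called, among them Mmp13, Mmp9, Serpine1, Cyr61, Pthlh and the activin subunit Inhba. For dPC12EVs against uPC12EVs the numbers were 47, 32 and 3 (Cnfn, Pink1 and Plcxd2). For uPC12EVs against PBS they were 47, 34 and 2 (Mmp13 and Mmp9). The unadjusted p was under 0.05 for 32, 23 and 25 of them. These lists were chosen on these samples, so they are not independent evidence of a direction.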

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

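The length correction and the test against a fold of 1.1 were chosen after seeing the data; the other alternatives were set before. Between dPC12EVs and uPC12EVs, dPC12EVs and PBS, and uPC12EVs and PBS, the number of genes called was 190, 349 and 62 with no filter on low counts, 37, 453 and 48 with only the 4 libraries compared, 29, 78 and 4 with DESeq2, 210, 442 and 35 at an adjusted p under 0.10, and 5, 24 and 4 against a fold of 1.1. Leaving out a library gave 45 to 220, 57 to 457 and 10 to 96, where a lone library is assumed to vary like the other groups. The genes shared between both comparisons with PBS were 32, 28, 3 and 22 under the first 4 of these, 4 against a fold of 1.1, 302 at an unadjusted p under 0.05, and 5 to 39 without a library; the covariance ran from 0.00438 to 0.00749, the upper values without a PBS library, where simulations with no effect gave means of 0.00538 and 0.00637. DESeq2 size factors, a mean of 5 CPM and a block for replicate number kept all 3 numbers within 1.5 times. Across genes, replicate numbers showed little pairing of the libraries (correlations -0.0048, 0.058 and -0.022 between groups). Sprr1a differed by replicate number (log2 fold change 0.41, adjusted p = 0.00862 by edgeR), so a pairing that shows in few genes is not excluded. Of 111 calls of named genes, 27 kept direction and threshold under each setting that gave a value, but 7 of these 27 (39 of the 111 calls) had no adjusted p with DESeq2. Of 43 list calls 21 did, an estimated correlation and fry left out. The test against a fold of 1.1 and the adjusted p under 0.10 are not among these settings. Over the settings with a value named genes gave 2550 values with the same outcome, 288 weaker, 99 stronger and 29 of the opposite sign. Lists, here with the estimated correlation and fry counted, gave 511, 132 weaker and 2 of the opposite direction, both of the ribosomal list. Of the 132 weaker, 43 came from the estimated correlation and 35 from fry. The direction of a list here is that of the camera test; the median of the mesenchymal list for dPC12EVs against uPC12EVs turned from 0.013 to -0.012 without uPC12EVs replicate 1 while its test kept direction. The sign turned without a library, with these ranges of log2 fold change, for genes past no threshold in the full data. For dPC12EVs against uPC12EVs they were Mx2 -2.09 to 1.06, Adrb2 -0.0863 to 0.17, Cdh1 -0.00169 to 0.0731, Il6 -0.24 to 0.38, Fos -0.27 to 0.0928 and Myc -0.00383 to 0.0411. For dPC12EVs against PBS they were Il6 -0.28 to 0.42, Fos -0.24 to 0.13 and Myc -0.0123 to 0.0997. For uPC12EVs against PBS they were Cxcl1 -0.54 to 0.0329, Mx2 -0.41 to 2.75, Rpl35 -0.00848 to 0.13, Rpl14 -0.00109 to 0.12, Egr1 -0.31 to 0.046, Cdh1 -0.0292 to 0.0758, Ngf -0.018 to 0.13, Il6 -0.33 to 0.36, Fos -0.0347 to 0.11 and Myc -0.0301 to 0.0817. Il6 there was also -0.0148 with the block, -0.00906 with the length correction and -0.015 with DESeq2. The ribosomal list median ranged from -0.0901 to 0.00572 for dPC12EVs against uPC12EVs and from -0.022 to 0.0811 for uPC12EVs against PBS. Fewer libraries leave fewer degrees of freedom; otherwise the cause was not tested. A change of the pseudocount was not run, since it applies to normalized units. Depth limits genes at low counts, such as Il6 with 18 to 27 counts and Th with 2 to 7.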

Other observations

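The tests of the ribosomal list without uPC12EVs replicate 2, of genes picked without uPC12EVs replicate 1, of the markers without Gata3 and of the position against the PBS library not used to pick genes were chosen after the result was seen, as was the list of cornified envelope genes; the intervals that decide the other tests were added later and moved outcomes only toward caution. Beyond the groups described above, 27 of 44 genes of the cornified envelope, the protein shell of squamous cells, were measured. Of these, 5 were lower with dPC12EVs than with uPC12EVs and none higher: Lgals7 (-0.36, SE 0.046), Fabp5 (-0.31, SE 0.048), Sprr1a (-0.54, SE 0.12), Cnfn (-0.84, SE 0.19) and Csta (-0.23, SE 0.057). Without uPC12EVs replicate 2 Sprr1a was -0.15 (adjusted p = 0.606). The median was -0.23, with 21 of 27 negative (camera adjusted p = 4.27e-11, and adjusted p = 0.289 with an estimated correlation). Because the list was chosen after these data were seen, its p-values in every comparison are descriptive. They cannot be read like those of the lists fixed in advance. Over the 16 members with a mean of at least 5 CPM it was -0.12, without dPC12EVs replicate 2 it was -0.35, and without uPC12EVs replicate 2 it was -0.12, so its size rests in part on members with low counts. Against PBS the median was 0.18 with uPC12EVs, where Fabp5 and Krt16 rose (adjusted p = 8.87e-08, and adjusted p = 0.366 with an estimated correlation). It was 0.074 without uPC12EVs replicate 2 (adjusted p = 0.0753), 0.11 without PBS replicate 1 (adjusted p = 0.0321) and 0.081 over the members with a mean of at least 5 CPM. With dPC12EVs against PBS the list did not pass (median -0.12, adjusted p = 0.161), and its median was 0.022 without PBS replicate 2 and -0.21 without PBS replicate 1 (adjusted p = 0.561 and 0.000503). The tetraspanins Cd9, Cd63 and Cd81 also fell between dPC12EVs and uPC12EVs (log2 fold changes -0.14, -0.12 and -0.16), in a list of EV machinery that did not pass as a whole (adjusted p = 0.0704 by camera and adjusted p = 0.311 with an estimated correlation).

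Of 9 adrenergic receptor genes, Adrb2 and Adra2b were tested, and neither passed in any comparison. Lists of CREB targets, p53 targets, oxidative stress, the unfolded protein response and nuclear genes of oxidative phosphorylation were called in no comparison. The summed markers of other cell types, relative to PBS, were 1.02 (95% interval 0.851 to 1.23) for endothelial, 0.919 (0.816 to 1.03) for immune and 1.06 (0.982 to 1.15) for fibroblast genes with dPC12EVs, and 0.873 (0.716 to 1.06), 0.912 (0.807 to 1.03) and 0.839 (0.769 to 0.916) with uPC12EVs. Adipocyte markers had 0 to 4 counts per library.

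The 105 genes called between dPC12EVs and uPC12EVs could reflect uPC12EVs replicate 2, which trends with transcript length. After the length correction 89.5% of them stayed called in the same direction (95% interval 82.0% to 94.7%), which argues against the trend as the source of most of the calls. Without that library 95.2% kept direction and an unadjusted p under 0.05 (89.2% to 98.4%) and 48 of the 105 stayed called, but 100 to 105 passed whichever library was left out, so this says nothing about its share. With genes picked on uPC12EVs replicate 2 and 1 dPC12EVs library, the other dPC12EVs library lay 0.048 (95% interval 0.036 to 0.064, 262 genes) and 0.10 (0.092 to 0.11, 130 genes) log2 units from uPC12EVs replicate 1 in the direction picked. Against uPC12EVs replicate 2 the medians were 0.15 and 0.18. The intervals are over genes and leave out the error of the single libraries compared. Within that limit uPC12EVs replicate 2 alone does not account for all of the difference, and its share among the 105 stays open.

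The ribosomal protein list (ribosomal_proteins, dPC12EVs against uPC12EVs) is different. Without uPC12EVs replicate 2 its median was 0.0057, which fits a difference carried by that library alone but does not single out its length trend. After the length correction it still passed (adjusted p = 0.0106, with 55.9% of the median kept, interval 37.7% to 59.6%), which was set in advance as evidence against the trend, but that test rests on the preset correlation (adjusted p = 0.677 with an estimated one), so trend and treatment were not separated for this list.

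The fall of cornified envelope genes between dPC12EVs and uPC12EVs was weighed in the same way. After the length correction the median was -0.20, or 87.8% of its size (interval 86.2% to 99.0%), which argues against the length trend. Without uPC12EVs replicate 2 it was -0.12, or 54.0% of its size (5.68% to 110%), and with an interval that wide the share owed to that library stays open. A difference in the state of the cultures, such as density, was not recorded in the labels and stays open beside an effect of the EVs.

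Of the 260 genes called between dPC12EVs and PBS, 235 had the same sign with uPC12EVs (90.4%), and uPC12EVs lay at a median of 0.389 of the way from PBS to dPC12EVs. With simulated uPC12EVs libraries equal to PBS, 52.3% to 67.0% had the same sign and the position was 0.0129 to 0.0838. In these simulations the genes called had their estimated changes as true effects and all other genes had none. Genes called partly through PBS error are then too few, so the simulated ranges may lie too low. With genes picked on 1 PBS library and measured against the other, uPC12EVs lay 0.0709 (95% interval 0.0479 to 0.0931) and 0.0914 (0.0738 to 0.124) log2 units toward dPC12EVs. This argues against chance in the PBS library used to pick the genes. The intervals are over genes and leave out the error of the PBS library measured against, and error common to both PBS libraries stays open. Of the 105 genes called between dPC12EVs and uPC12EVs, uPC12EVs lay between PBS and dPC12EVs in 44 and on the other side of PBS in 59, by the sign of the fitted fold changes. Those genes were picked for a difference between dPC12EVs and uPC12EVs, so error in uPC12EVs favours the far side of PBS. No simulated value was set beside this split, so nothing is concluded from it. That EVs of both kinds act in part alike rests on the genes called against PBS. A shared difference in handling between PBS and EV cultures was not tested and stays open.

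RNA carried in by the EVs was tested as a source of the genes higher with dPC12EVs. The summed counts of 33 sympathetic and chromaffin markers were 0.985 times those in PBS, with an interval up to 1.17, and 0.880 without Gata3, with an interval up to 1.15. Gata3, which breast epithelium also expresses, made up 59.7% of the sum, and 15 markers had 0 counts in all 6 libraries, where 3 counts allow 0.0840 CPM with dPC12EVs. Single markers at low counts went both ways. Scg2 had 3 and 5 counts with PBS and 10 and 11 with dPC12EVs, and Slc6a2 had 4 and 9 with PBS and 3 and 3 with dPC12EVs. The sum argues against bulk PC12 RNA, and RNA loaded selectively into EVs stays open, because EV RNA was not measured.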
